A study of Mus musculus with 3 samples.

How the data were processed

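Ets-1 ChIP-seq libraries of Min6 cells infected with a control or an Ets-1 adenovirus and an input library were analysed from 3 deposited files: a peak list for each precipitated library and a table that compares them. Per the labels' protocols, cells were grown in 25 mM glucose, infected for 24 h and crosslinked in 1% formaldehyde for 10 min, and libraries were sequenced in pairs. Per the submitters' processing notes, FastQC, Trimmomatic, BWA 0.7.12 and MACS2 2.1.0 were used with build mm10; the settings and whether the input served as control in peak calling are not given in the sources used here. The labels do not state the virus of the input.

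In the peak lists, the authors deposited for each peak a fold enrichment (a ratio), a −log10 p-value, a −log10 q-value and a score, per the file headers. These belong to each peak and were used only to describe, rank or filter within a list. In the comparison table, the authors deposited read counts per region and library, RPM values computed as the count plus 1 scaled to the library's total, a ratio of these RPM values and its log2 value, per the file headers and the values. Annotation classes, nearest genes and distances to start sites are those of the deposited files. Their transcript coordinates were the same as those of GENCODE M21 for 98.9% of the transcripts shared with it in the comparison table, and no peak lay beyond the end of a GRCm38 chromosome. Peak list starts were 0-based and were raised by 1.

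The lists were cut at a low threshold. The largest p-value was 0.00460 for the control virus and 0.00499 for the Ets-1 virus, and the largest q-value was 0.764 and 0.820; 88.3% and 85.1% of peaks shared that largest q. Read totals were recovered from counts and RPM, and every region gave the same total within 1%. Even counts made up 72.0% and 74.5% of nonzero counts in the Ets-1 and control virus libraries and 19.0% in the input, so both mates appear to have been counted in the precipitated libraries. Intervals of read ratios were therefore computed on fragments, with 2 reads to a fragment and rounding up, by the exact conditional binomial; shares have exact Clopper-Pearson intervals at the 95% level. A ratio against 0 reads was computed against a floor of 3 reads per library. It has no interval and is not a lower limit of the true ratio. No ratio is given where both libraries hold 3 or fewer.

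Groups were taken from the sample titles, with 1 library in each, and all comparisons are descriptions of these libraries. Peak lists were compared by overlap of at least 1 bp, set beside 100 seeded circular shifts within each chromosome. Ties in q were broken by fold and then at random with a fixed seed. Gene lists, 19 in number, were fixed before the data were examined, and the share of members with a promoter peak was ranked among 10000 random lists matched in 10 bins of gene length. The background was the 19054 genes with a symbol named as nearest gene in any file. ETS words were counted in 200 bp windows at summits on chromosomes 1 to 19 and X, and 2 kb to either side. Promoter windows without listed regions, 149738 in number, were drawn around 54086 protein-coding start sites for matched comparisons.

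Genes named in the text followed a rule fixed before the data were examined: Ets1 and 10 further β-cell genes whatever they showed; per peak list the 10 genes with the highest fold among promoter peaks on chromosomes 1 to 19 and X, without predicted genes and names starting Gm or ending Rik; the 10 promoter genes with the largest change in each direction of the comparison table; and up to 4 members per gene list and class of occupancy, of which the text gives examples. Some items that the rule or a threshold selects are not reported here. Alternatives were stricter q and fold thresholds, equal numbers and top peaks, other overlap rules, other promoter definitions, unmatched lists, other words and windows, and leaving out scaffolds, chromosome Y or the widest 1% of peaks; a q of at most 0.05, the top 3000 peaks, satellite removal and a minimum of 5 reads were added after seeing the data. The −log10 q alternative for the comparison table was not run, since that table has no q column.

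Tested on simulated data, a planted overlap of 20% was recovered as 20.3% over 20000 intervals, 4.50% of random gene lists exceeded the 95th percentile over 19055 genes, and 97.2% of intervals held a true ratio of 1. The simulated counts were independent fragments without paired reads or PCR copies, so coverage of the intervals on the real reads was not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, matplotlib 3.10.9 and bedtools 2.31.1 were used.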

Results

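Chromatin of Min6 cells, an insulin-secreting mouse β-cell line derived from an insulinoma, was precipitated with an antibody against the transcription factor Ets-1 and sequenced in pairs (ChIP-seq). Cells had been infected for 24 h with a control adenovirus that carries GFP or with an adenovirus that overexpresses Ets-1, and an input library of chromatin without precipitation was sequenced as well. Each of the 3 groups held 1 library, so no difference between them has a replicate check and no p-value is given. The deposited counts and RPM values imply 1938473 reads for the Ets-1 virus library, 1775757 for the control virus library and 3937473 for the input. Most listed regions rest on very few reads: 91.0% of the 543367 compared regions held 2 or fewer reads in the Ets-1 virus library and 89.3% in the control virus library. Coordinates are those of mm10, 1-based. Folds are ratios of reads scaled to these totals. Their 95% exact binomial intervals, like all intervals here, cover counting error only and leave out variation between libraries. Reads amplified by PCR without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. Ratios against a floor of 3 reads have no interval.

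The first question was where Ets-1 signal lay at β-cell genes with endogenous and with overexpressed Ets-1. At Ets1 itself, 15 regions were listed across 5 promoter and 10 intronic positions, none annotated as an exon, and no region held more than 2 reads in either library. Txnip, an inhibitor of thioredoxin that high glucose induces, had promoter peaks in both lists. The strongest, as deposited, lay in a region (chromosome 3, 96558209 to 96558484) with a fold of 4.98 over local background with the control virus and 4.17 with the Ets-1 virus, at −log10 q of 2.103 and 1.42. It held 17 and 10 reads, an Ets-1 virus to control virus ratio of 0.539 whose interval of 0.134 to 1.69 spans 1. These strongest peaks lay 248 bp with the control virus and 275 bp with the Ets-1 virus from the nearest annotated start site. Another region annotated to the Txnip promoter (chromosome 3, 96559556 to 96560529) held 47 reads with the control virus and 6 with the Ets-1 virus. It held 11 in the input and was called with the control virus alone. The ratio there was 0.12 (95% interval 0.0221 to 0.377), and the region was 9.47 times the input with the control virus and 1.11 times with the Ets-1 virus.

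The insulin genes and Mafa, a transcription factor of mature β cells, had promoter reads in both precipitated libraries or with the Ets-1 virus alone. The Mafa promoter (chromosome 15, 75746706 to 75747751) held 39 reads with the Ets-1 virus and 32 with the control virus, a ratio of 1.12 (0.564 to 2.36). It held 20 in the input and was 3.96 and 3.55 times the input after scaling. The Ins2 promoter (chromosome 7, 142679634 to 142680016) held 28 and 19 reads, a ratio of 1.35 (0.530 to 3.23), against 21 in the input, which is 2.71 and 2.01 times the input after scaling. These ratios to input have no interval. Both promoters also stood out in the input, where 99.9% of compared regions held 2 or fewer reads. The Ins1 promoter (chromosome 19, 52264723 to 52265002) held 10 reads with the Ets-1 virus, 0 with the control virus and 2 in the input. After scaling, its Ets-1 virus reads were 3.05 times the control virus floor of 3 reads. At Neurod1, a β-cell transcription factor, the promoter held 4 and 2 reads. Foxo1, a mediator of insulin signalling, had a single distal region with 0 and 3 reads. Pdx1 and Nkx6-1, regulators of β-cell identity, had no promoter region. A distal region of Nkx6-1 held 7 reads with the Ets-1 virus and 0 with the control virus, or 2.14 times that floor. No region of Slc2a2, the glucose transporter gene, held more than 4 reads. At Neurod1, Foxo1, Pdx1 and Slc2a2 a difference was not detectable at this depth. For Ins1 and Nkx6-1 it was not tested whether the difference exceeds counting error.

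**Figure D1:**
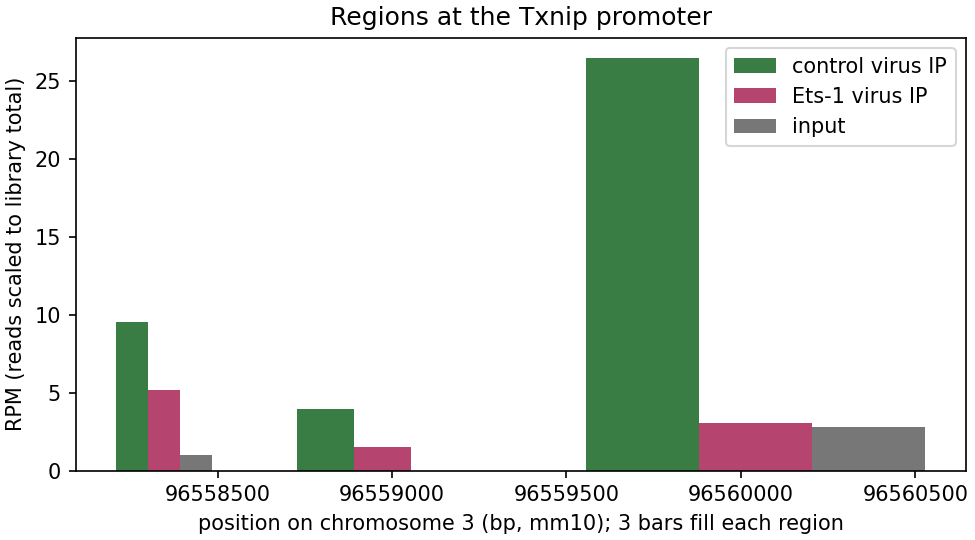
RPM, the reads scaled to each library's total (vertical axis) in the 3 regions listed at the Txnip promoter on chromosome 3 (horizontal axis, mm10 position), for the control virus, Ets-1 virus and input libraries, 1 library each; the 3 bars together span each region. The region with the most control virus reads holds 47, against 6 Ets-1 virus reads.

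With predicted genes left out, the 10 leading promoter genes by fold differed between the lists except for Irs1. With the Ets-1 virus, the authors' deposited table then ranked Rpl32, a ribosomal protein gene, first with a fold enrichment of 7.64 over local background, followed by Irs1 at 7.46, Arid5b at 7.21, Pif1 at 5.86 and Mlxipl at 5.86; Irs1 and Mlxipl encode an insulin receptor substrate and a glucose-responsive transcription factor. Rnf187, Dtwd2, Zmpste24, Rpl9 and Rfc2 completed the 10. The Rpl32 promoter (chromosome 6, 115808553 to 115809264) held 29 reads with the Ets-1 virus and 4 with the control virus, a ratio of 6.64 (1.60 to 61.9). The Rpl9 promoter (chromosome 5, 65391145 to 65391655) held 14 and 0 reads, or 4.27 times the floor of 3 reads. Irs1 (chromosome 1, 82289782 to 82290494) held 64 and 57 reads, a ratio of 1.03 (0.592 to 1.73), against 18 in the input. Mlxipl held 65 and 36 reads, a ratio of 1.65 (0.919 to 3.17). Both intervals span 1.

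With the control virus, the authors' deposited table placed Tyr first at a fold of 19.4, then Emx1 at 17.6, Hoxd13 at 17.2 and Fgf21 at 9.22, followed by Irs1, Dnmt3a, Fgf5, Mstn, Dnase2b and Cherp. Tyr encodes tyrosinase of pigment cells, and Emx1 and Hoxd13 are homeobox genes of forebrain and limb. Tyr (chromosome 7, 87492325 to 87492781) held 142 reads with the control virus and 2 with the Ets-1 virus, a ratio of 0.0129 (0.000322 to 0.0742), Hoxd13 held 182 and 4, and Emx1 held 174 and 22. The input held 4, 17 and 12 reads in these 3 regions. Foreign or amplified DNA is a candidate explanation for them, given under the other observations, so they cannot be read as Ets-1 binding lost on overexpression.

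Peaks of both lists lay mostly outside genes. Of 339856 control virus peaks, 52.1% were distal intergenic, 34.6% intronic and 7.73% at promoters (95% exact interval 7.64 to 7.82); of 237322 Ets-1 virus peaks the shares were 53.5%, 33.4% and 7.66% (7.56 to 7.77). Among peaks with a deposited q of at most 0.05, promoters made up 15.1% (13.9 to 16.4) of 3281 Ets-1 virus peaks and 9.43% (8.37 to 10.6) of 2810 control virus peaks. The gap appeared at intermediate read numbers: in regions with 8 to 11 reads, 16.5% (14.9 to 18.2) lay at promoters with the Ets-1 virus and 9.63% (8.26 to 11.1) with the control virus, while with 1 to 2 reads the shares were 7.20% and 7.57%. It was not seen with 20 or more reads, where the shares were 26.7% (19.01 to 35.5) and 30.2% (22.5 to 38.9). The promoter share of these listed regions also rose with read number in the input, from 9.08% with 1 to 2 reads to 23.4% (19.05 to 28.2) with 3 to 4. Promoters of 7174 named genes carried an Ets-1 virus peak and those of 9268 a control virus peak, with 4620 in both against 3489 expected of independent lists. At a q of at most 0.05 these were 317, 143 and 23 genes, and 305, 131 and 11 without peaks that hold the satellite word described below. Only 1.38% of Ets-1 virus peaks and 0.827% of control virus peaks passed that threshold, which was added after seeing the data, and the 2 promoter shares come from single libraries.

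**Figure D2:**
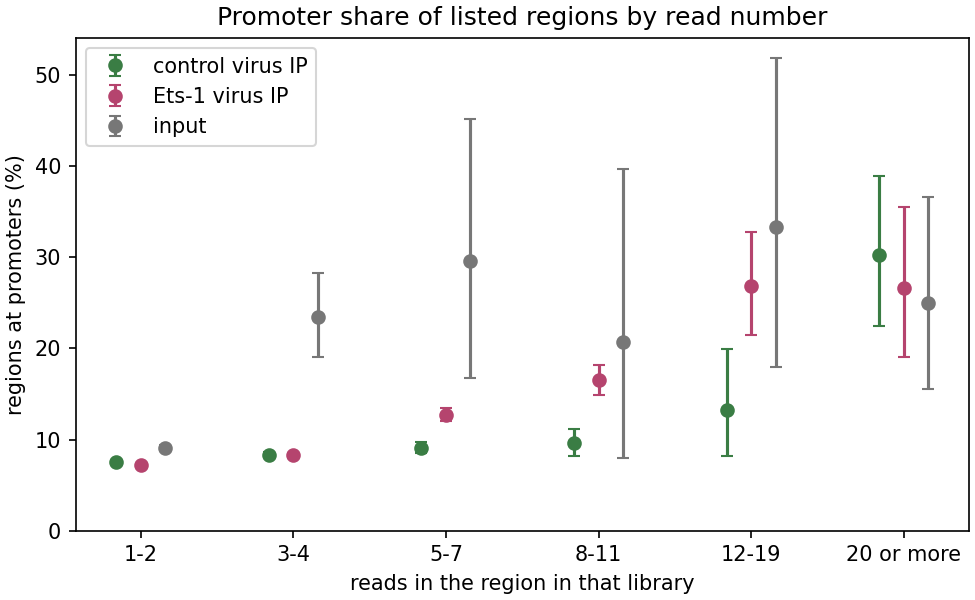
Share of listed regions at promoters (vertical axis, percent) by the number of reads the region holds in that library (horizontal axis), for the control virus, Ets-1 virus and input libraries, with 95% exact binomial intervals. Regions were called in the same library, or for the input in either list. Regions with the satellite word are left out. The precipitated libraries are close below 5 reads, separate at 8 to 11 reads, at 9.63% and 16.5%, and overlap again at 20 or more. The input is above both at 3 to 4 reads.

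The direct comparison of both viruses, as deposited, listed 33328 regions called in both libraries, 203809 called with the Ets-1 virus alone and 306230 with the control virus alone. The 10 promoters with the largest rise with the Ets-1 virus were those of Prepl, Mrps28, Atp6v1f, Ythdc2, Tcf4, Pde1a, Tdrd7, Rpl9, Slc38a2 and Ppid. Prepl held 22 reads with the Ets-1 virus and 0 with the control virus, or 6.72 times the control virus floor. Mrps28, a mitochondrial ribosomal protein gene, and Atp6v1f, a proton pump subunit gene, each held 16 against 0, or 4.89 times that floor. In the other direction stood Tyr, Hoxd13, Zfp280d, Gtpbp4, Olfr905, Dnase2b, Rfc1, Cherp, Slc22a8 and Mss51. Zfp280d held 18 reads with the control virus and 0 with the Ets-1 virus, or 6.55 times the Ets-1 virus floor. Across all regions, 39.6% were higher with the Ets-1 virus, and among regions with 5 or more reads in either library, an alternative added after seeing the data, 49.4% were. Of the Ets-1 virus intervals, 14.1% were overlapped by a control virus interval, against 7.15% after random circular shifts, and of the control virus intervals 9.85% against 5.00%. An input shared by both peak calls could raise this overlap without any binding, which was not tested. In regions called in 1 library alone the medians were 2 reads in that library and 0 in the other.

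**Figure D3:**
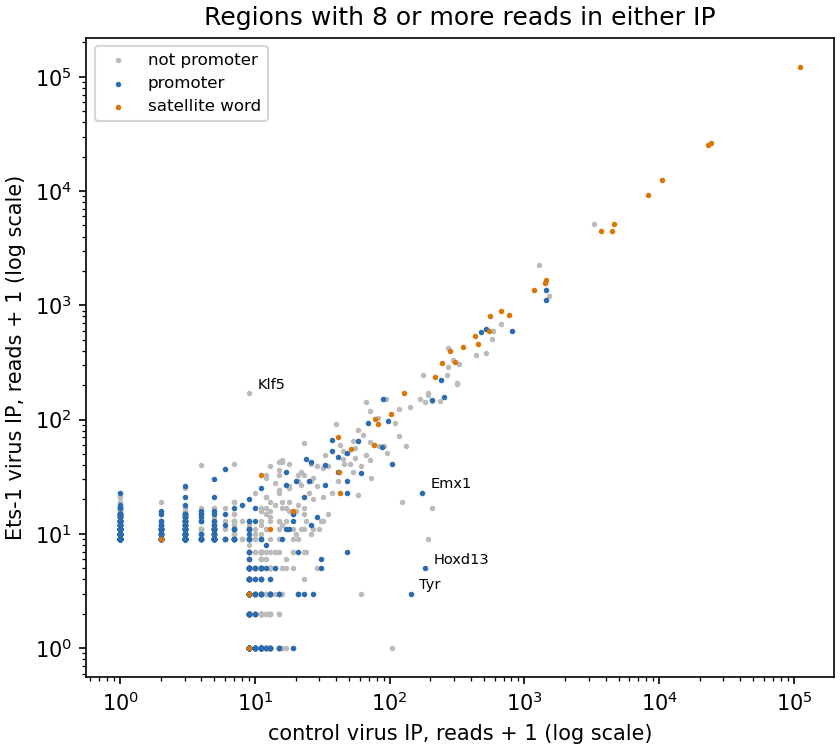
Reads plus 1 in each region on log axes, control virus library (horizontal) against Ets-1 virus library (vertical), for regions with 8 or more reads in either; colours mark promoters, other regions and regions with the satellite word, and named points are promoter and distal regions with at least 50 reads in 1 library and at least an 8-fold difference. Tyr, Hoxd13 and Emx1 lie low and Klf5 lies high, while satellite regions follow the diagonal.

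The gene lists asked which groups carried promoter peaks. Counts are out of the members named as nearest gene of any listed region, which can be fewer than the list holds. By the deposited lists, olfactory receptor genes, whose expression was not measured here, stood highest by percentile but not by share. A control virus promoter peak was listed for 683 of 1074 and an Ets-1 virus peak for 530. The percentile was 100 among 10000 random lists matched on gene length in both libraries. Insulin signalling and FoxO genes had 16 and 13 of 23 members with a peak (percentiles 93.3 and 90.9), led by Irs1 and Tsc2. β-cell identity genes, a list of 27, had 12 and 7 of 22 (72.9 and 30.8), with Mafa, Ins2 and Pax6 in both lists and Ins1 and Nkx2-2 with the Ets-1 virus alone. Glucose sensing genes, a list of 23, had 8 and 8 of 20 (8.67 and 34.5), with Abcc8 in both and Pcx with the Ets-1 virus alone; granule genes, a list of 25, had 6 and 7 of 22 (1.23 and 23.6), with Scg2 in the control virus list alone and Scg3 in the other alone. ETS family genes, a list of 26, had 12 and 9 of 22 (59.2 and 51.4), none past 4 reads among the members named, and genes described elsewhere as Ets-1 targets, a list of 23, had 9 and 8 of 21 (28.2 and 50.0).

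Among the other groups, unfolded protein response genes had 9 and 8 of 16 members with a peak (70.5 and 83.0), antioxidant genes 8 and 7 of 16 (57.5 and 72.8), progenitor and disallowed genes 7 and 9 of 18 (23.9 and 88.3) and cell cycle genes 7 and 8 of 15 (45.0 and 89.4). These lists held 22, 19, 19 and 25 genes, so that over the whole cell cycle list the shares were 28% and 32%. Apoptosis genes had 4 and 4 of 16 (5.22 and 22.5), interferon response genes 5 and 5 of 15 (19.2 and 49.2), ribosomal protein genes 22 and 17 of 44 (87.1 and 87.2) and oxidative phosphorylation genes 23 and 17 of 48 (64.8 and 55.6), from lists of 19, 22, 44 and 48. Markers of other cell types carried peaks as well: acinar and duct markers had 7 and 7 of 13 (68.6 and 89.5), liver and muscle genes 9 and 7 of 14 (90.4 and 87.5), endothelial, immune and fibroblast markers 5 and 3 of 12 (26.0 and 15.1) and other islet hormone cell markers 3 and 1 of 9 (29.6 and 8.94), from lists of 17, 14, 14 and 11. At a q of at most 0.05 the members left with the Ets-1 virus were few but included Xbp1 and Pdia6 of the unfolded protein response (percentile 98.2), Cat, Sod1 and Txnip of the antioxidant list (99.9), Hk1 and Igfbp4 of the disallowed list (98.1), Cdk2 and Mcm7 of the cell cycle list (98.4) and Irs1 and Tsc2 of the insulin signalling and FoxO list (95.9). Each of these 5 counts rests on 3 or fewer genes. The threshold was added after seeing the data, 19 lists were ranked, and the random lists were matched on gene length but not on promoter GC content. No list passed the 95th percentile with the control virus, where Txnip and Irs1 also passed the q threshold. Olfactory receptors then stood at percentile 14.3 with the Ets-1 virus (10 genes) and 30.6 with the control virus (6 genes).

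The ETS recognition word C[AC]GGAAGT was rare at summits and nearly as frequent 2 kb away. It occurred in 1.39% of 200 bp windows at Ets-1 virus summits against 1.33% in flanks, a ratio of 1.04 (1.00 to 1.09), and in 1.33% against 1.37% at control virus summits, a ratio of 0.969 (0.935 to 1.00). The reversed word, of the same letters, occurred in 1.31% and 1.33% of the summit windows. At promoter peaks with a q of at most 0.05, the word occurred in 4.05% of Ets-1 virus windows, 3.61 times the flanks (1.65 to 8.34), and in 1.90% of control virus windows, 1.24 times (0.318 to 4.28). The variant CCGGAAGT was 2.37 times as frequent as in flanks at all Ets-1 virus promoter peaks (1.73 to 3.26) and 1.71 times at control virus promoter peaks (1.27 to 2.32). Among the 10 leading Ets-1 virus promoters, Rpl32 alone held the word, as CCGGAAGT on the minus strand at chromosome 6, 115808813 to 115808820. None of the 10 leading control virus promoters did, nor did any of the 10 promoters with the largest rise with the Ets-1 virus or of the 10 in the other direction. Flanks lie farther from start sites than promoter summits do, and the difference between the viruses was not tested.

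Relative to input, precipitated reads were concentrated in major satellite DNA, the pericentromeric repeat of the mouse. The 213 regions with the satellite word GAAAACTGAAAA held 11.4% of Ets-1 virus reads (95% exact interval 11.3 to 11.5), 11.3% of control virus reads (11.2 to 11.3) and 1.62% of input reads (1.60 to 1.63). A single region on chromosome 2 (98666109 to 98667430), annotated as the promoter of Gm10800, held 122344, 110707 and 38590 reads. Satellite reads were 7.05 times the input with the Ets-1 virus (6.97 to 7.14) and 6.96 times with the control virus (6.87 to 7.05), and the viruses differed by a factor of 1.01 (1.00 to 1.02). Outside satellite, the listed regions held 0.242 times the input reads that even coverage of the genome would give, for a reason that was not tested.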

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

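The q threshold of 0.05, the top 3000 peaks, the removal of satellite and the minimum of 5 reads (alone or with the fold) were chosen after seeing the data; the other settings were planned. No paired analysis was possible because each group holds 1 library. Regions held a median of 2 or fewer reads in each library. The number of control virus peaks fell from 339856 to 114 at a −log10 q of at least 5, 127 at a fold of at least 5 and 2810 at a q of at most 0.05; for the Ets-1 virus from 237322 to 113, 162 and 3281, so that the longer list was that of the control virus as deposited and that of the Ets-1 virus at q of at most 0.05 and at fold of at least 5. The share of Ets-1 virus intervals overlapped was 5.93% by reciprocal overlap, 5.41% by summits within 100 bp, 61.9% at −log10 q of at least 5, 12.5% with equal numbers, 8.39% in the top 1000, 13.6% without the widest 1% and 3.30% at q of at most 0.05; for the control virus these were 4.14%, 3.78%, 64.4%, 12.5%, 8.75%, 9.51% and 3.99%. At −log10 q of at least 5, 26 of 84 Ets-1 virus and 30 of 87 control virus intervals held the satellite word. Without them the shares overlapped were 46.6% and 49.1%, and at q of at most 0.05 without satellite 2.46% and 2.91%. After circular shifts the Ets-1 virus share was 0.733% in the top 1000 and 0.322% at q of at most 0.05. The observed share was 11.4 and 10.3 times these, against 1.97 times as deposited. For the control virus the ratios were 21.5, 15.2 and 1.97. Promoter shares were 45.6%, 12.2%, 9.43%, 8.05%, 9.83% and 5.65% for the control virus and 45.1%, 20%, 15.1%, 14.0%, 14.8% and 5.69% for the Ets-1 virus at −log10 q of at least 5, in the top 1000, at q of at most 0.05, there without satellite, in the top 3000 and within 1 kb of a start site. Without satellite the shares at −log10 q of at least 5 fell to 16.7% and 18.8%. Promoter genes numbered 20, 143 and 17934 with the control virus, 17, 317 and 16144 with the Ets-1 virus and 13, 23 and 15024 in both, at −log10 q of at least 5, at q of at most 0.05 and for nearest genes at any distance. Without satellite they were 8 and 131 with the control virus, 5 and 305 with the Ets-1 virus and 1 and 11 in both at the first 2 thresholds. Gene lists above the 95th percentile, 1 of 19 in each library as deposited, were 2 in each without length matching, 4 with the control virus within 1 kb, and 0 with the control virus and 5 with the Ets-1 virus at q of at most 0.05. Of the single gene list values under all alternatives run, as percentage points over random lists, 253 stayed within their counting intervals and 13 did not. These intervals are wide and strict thresholds leave few members, so staying within them is weak evidence of stability. Apoptosis genes with the control virus counted as within, though they moved from −20.5 to −0.153 at −log10 q of at least 5. The share of regions higher with the Ets-1 virus was 19.4% among those with a fold of at least 5, a threshold that 4 reads against 0 met for the control virus and 5 for the Ets-1 virus. It was 49.7% among those that also held 5 or more reads and 49.4% among all with 5 or more reads. The ETS word ratio of summits to flanks for all peaks was 1.097, 1.01, 0.618 and 0.907 with the control virus for CCGGAAGT only, the core word, the top 1000 and q of at most 0.05, and 1.37, 1.45 and 1.33 with the Ets-1 virus for CCGGAAGT only, the top 1000 and q of at most 0.05. For promoter peaks it was 1.71 for CCGGAAGT only and 0 in the top 1000 with the control virus, and 2.37, 3.44 and 3.61 with the Ets-1 virus for CCGGAAGT only, the top 1000 and q of at most 0.05. In the top 1000 these rest on 0 of 121 windows against 2 of 236 flank windows with the control virus and on 7 of 198 against 4 of 389 with the Ets-1 virus (interval 0.874 to 16.02, which spans 1). Apart from satellite and the reads that the fold threshold needs, the cause of these shifts was not tested. Leaving out scaffolds and chromosomes Y and M moved none of the peak numbers, overlap shares, promoter shares, promoter genes, gene list values or the share of regions higher with the Ets-1 virus beyond its counting interval or by 1.5 times. The ETS words were counted on chromosomes 1 to 19 and X only.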

Other observations

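The satellite tests and the coding exon test were chosen after their results were seen, the explanation tested with permuted words was reworded after its result was seen, and the comparisons of C[AC]GGAAGT, of single other words and of CCGGAAGT matched on distance were not planned. The tests of CCGGAAGT matched on GC content and of the other words as a group were set before. Regions with at least 50 reads and at least an 8-fold difference were chosen after their values were seen, and 1 was stronger with the Ets-1 virus: a distal region 25376 bp from the start of Klf5, a zinc finger transcription factor gene (chromosome 14, 99324530 to 99325536), with 169 reads against 8 and 4 in the input. It held the ETS word.

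Promoters were a larger share of the regions with 8 to 11 reads with the Ets-1 virus than with the control virus (16.5% against 9.63%), and not of those with 20 or more reads (26.7% against 30.2%). In the input too the share was higher with 3 to 4 reads (23.4%) than with 1 to 2 (9.08%). The mean GC content of promoter regions also differed between the libraries. With 5 or more reads it was 51.4% with the Ets-1 virus and 45.4% with the control virus, and with 8 or more reads 53.8% and 46.6%. Whether this difference bears on the promoter shares was not tested. Among 1545 promoter regions with 5 or more Ets-1 virus reads, 2.39% held CCGGAAGT (95% exact interval 1.69 to 3.29), 3.40 times the 0.705% of windows matched on GC content and 2.94 times the 0.815% of windows matched on distance to the start site as well, which is also the matching for the control virus and the other words below. Among 1085 such control virus regions, 0.184% held it (0.0223 to 0.664), against 0.386%. For the word C[AC]GGAAGT the shares were 3.04% with the Ets-1 virus (2.24 to 4.02) against 2.22% of matched windows, 1.37 times, and 1.75% with the control virus (1.06 to 2.72) against 1.77%. By observed minus expected count, matched on GC content only, CCGGAAGT ranked 1 among 1080 CpG-holding permutations of its letters. For the excess of this word, the rank argues against GC and CpG content alone. A rank by difference favours words that are frequent at promoters, however. It also cannot say why promoters were a larger share, since it was taken within promoter regions. Words of other promoter factors were also raised with the Ets-1 virus as a group: any of 5 words occurred in 14.4% (12.7 to 16.2) against 10.95%, or 1.31 times. With the control virus they occurred in 6.36% (4.98 to 7.98) against 6.56%, or 0.970 times. Singly, AAGATGGC was raised by 1.98 times, at 3.04% (2.24 to 4.02) against 1.53%, which is more than C[AC]GGAAGT and less than CCGGAAGT. For TGACGTCA (1.67 times), GCATGCGC (1.56), CCAATCA (1.28) and GGGCGGGG (1.11) the matched share lay within the interval. Sampling of active promoters whatever the factor may account for some of the excess, and recruitment of Ets-1 to ETS sites is a hypothesis that remains open beside it.

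Satellite DNA was enriched over input in both precipitated libraries. Repeat copies collapsed in the reference would raise all libraries alike, but the smaller ratio to input was 6.96. The Ets-1 virus to control virus ratio was 1.01, with an upper limit of 1.02 that covers counting error only. With 1 library per group the variation between precipitations is unknown, so binding that grows with the Ets-1 dose and a bias shared by both precipitations cannot be told apart. Satellite binding already complete with endogenous Ets-1 was not tested.

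A set of 7 regions with at least 50 control virus reads were at least 8-fold weaker with the Ets-1 virus, among them Tyr, Hoxd13 at 2 positions, Kcna1 and Emx1. Coding exons covered at least 50% of the length of 4 of the 7, or 57.1% (95% exact interval 18.4 to 90.1), against 1.63% of other control virus peaks with a q of at most 0.05, so foreign or amplified DNA fragments in that library are a candidate explanation. Loss of Ets-1 binding on overexpression cannot be told apart from this with 7 regions, since 1 of them held the ETS word, 14.3% with an upper limit of 57.9%.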
